A study of Caenorhabditis elegans with 12 samples.

How the data were processed

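RNA was measured in 12 samples of *Caenorhabditis elegans*, 3 each from the paternal strain, the maternal strain, the mendelian F1 and the non-mendelian F1. Per the labels, each sample held 60 whole young adult hermaphrodites grown at 25 °C on bacteria, RNA was extracted with an organic reagent and columns, and the Cy3-labelled product was hybridized to one-colour Agilent arrays. The labels give neither the genotypes of the strains nor whether the samples of a group were separate cultures. Per the file headers, the intensity values of the scanner files were made with Agilent Feature Extraction 11.5.1.1, which subtracted the background and detrended each array, and they were not normalized between arrays. The flags in the same deposited files (other values, 0 or 1) mark spots well above background, saturated spots and outlier spots. The authors also deposited a table of intensity values with 12 columns and 57925 lines, whose columns hold identical quantiles and a common median of 14.2684. The steps behind that table are not stated, and its range shows a linear scale, so log2 was taken before use.

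Each column of the authors' table was set against all 12 scanner files after pairing all 57925 lines by systematic name. The best correlation was at least 0.9984 for every column and the second best at most 0.9893. The 3 paternal columns matched their own files and 9 columns matched a file of another group, whose own-label correlations were 0.9692 to 0.988. Columns named mendelian F1 matched maternal files, columns named maternal matched non-mendelian F1 files, and columns named non-mendelian F1 matched mendelian F1 files. Groups followed the sample record of each scanner file, and the table entered only as an alternative. The arrays lay on 2 slides, read from the file names: 8 arrays (paternal 1 and 3, mendelian F1 3, maternal 1 to 3, non-mendelian F1 2 and 3) and 4 arrays (paternal 2, mendelian F1 1 and 2, non-mendelian F1 1).

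Each array held 62976 spots, of which 61657 were not controls, for 57925 probes and 46783 distinct genes. Of these probes 15365 target 21U-RNAs, 2532 lie on more than 1 spot and were averaged, and 636 have a sequence that also serves another gene, which the text calls a shared probe. The reference table, used for names only, gave a symbol to 56155 probes and none to 1770. Positions are the spans given in the scanner files, on build ce6 (WS190) per the file headers, and were not mixed with the reference. No spot was saturated, and 24 to 116 spots per array were outliers. Probes well above background made up 46.6% to 52.9% of an array (mean 49.6%), and the 75th percentile of the signal ranged from 184 to 587, so dim genes were measured with little precision.

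The log2 of the processed signal was taken and the 75th percentile of each array, over 24800 probes well above background on all 12 arrays, was subtracted. Probes well above background on at least 3 arrays were kept (30305), and each gene was represented by the probe with the highest mean, which left 20348 genes, 19460 of them named by the reference and 15880 protein-coding. For called genes with more than 1 probe, probes differed in sign for 3 of 331 genes between the parental groups and 1 of 190 between the F1 groups. The limma package (3.58.1, R 4.3.3) fitted a mean per group to all 12 arrays (8 residual degrees of freedom, 1.84 prior degrees of freedom). Each contrast was moderated by empirical Bayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes and lists come from limma. The contrasts were the 6 pairs of groups and both F1 groups against both parental groups.

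The 31 gene lists were written from general knowledge before any value was seen: spindle pulling force complex, body wall muscle, pharynx, intestine, vitellogenins, pan-neuronal, neurotransmitter identity, neuropeptides, cuticle collagens, germline mitosis and meiosis, oocyte and eggshell, major sperm proteins, other sperm genes, early embryo zygotic, male neurons, larval moult, heat shock, unfolded protein response, antimicrobial and pathogen response, intracellular pathogen response, detoxification, oxidative stress defence, cytosolic ribosome, oxidative phosphorylation, fatty acid metabolism, histones, cell cycle, small RNA silencing, dosage compensation and sex determination, insulin and dauer signalling, and chemoreceptors. Camera of limma tested each list with at least 5 tested members, with a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the residuals. Members were also adjusted over the list alone.

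The position of an F1 sample on the parental axis was the slope of its difference from the mean of the parents on the difference between the parents, over the genes called between them, and the F1 groups were compared by an exact permutation test. The split of the axis by gene set and the tests of the X chromosome were added after the data were seen. Chromosomes were compared with Fisher's exact test and, for the X chromosome, with 10000 random lists of genes not placed on the X chromosome, matched in number and mean expression. The size of the X-linked falls was measured on 1 maternal and 1 paternal array that had no part in choosing them, for each of the 9 such pairs, and the bounds of the tests of males and of the dose of the X chromosome were set again 2 times after these values had been seen. Named genes followed a fixed rule: gpr-1, gpr-2, lin-5 and unc-119 in every group, and the 10 largest called rises and falls in the comparison of the parents and that of the F1 groups, or 5 in each other comparison. They had to carry a gene name, lie above background on every array of at least 1 group and separate the arrays of the groups. This separation fixes the direction of each gene named by size on either slide taken alone. Where fewer than 10 genes were called, the 5 rises and 5 falls with the lowest p were taken, and each passing list gave up to 4 members with the lowest p. The 4 X-linked genes named for the maternal fall were taken afterwards, as those with the lowest p.

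The comparisons, tests, samples and most alternatives were chosen before the data were examined. The alternatives changed the background correction, scaling, filter, choice of probe, variance model, samples in the fit, slide, replicate number, array weights and source of the values, and left out each sample in turn. Added later were scaling over all probes, protein-coding genes only and the authors' table under its own labels. The procedure was tested on simulated data with 200 changed genes among 20348. In the parental comparison it recovered 40 of 100 genes changed by 1 log2 unit and 78 of 100 changed by 2, with 12 unchanged genes among 130 called. In the F1 comparison it recovered 36 and 76 of 100, with 13 unchanged among 125. Simulated axis positions of -0.25 and 0.25 were read as -0.247 and 0.246, and 1 list shifted by 0.5 was the only list passing. The simulated noise was independent between genes, so the simulation does not test false passes of lists whose genes move together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.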

Results

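Worms in which the chromosome sets of the 2 parents are sorted into different cell lineages allow the contribution of each parental genome to be read tissue by tissue. The arrays measured RNA from whole young adult hermaphrodites of *Caenorhabditis elegans* in 4 groups: the paternal strain, the maternal strain, their mendelian F1 progeny and non-mendelian F1 progeny. Per the labels, the non-mendelian F1 carried the paternal genotype in body wall muscle, intestine and germline and the maternal genotype in the nervous system. Each group had 3 samples of 60 worms, each on its own one-colour array, and the small number of arrays limits the precision of every estimate. Differences below are log2 values ± standard error from limma, and levels are log2 signal relative to the 75th percentile of the array, mean ± SD over the 3 arrays of a group. All p-values measure only the spread between these samples, which may be partly technical because the records do not state whether the 3 samples of a group were separate cultures. Transcript levels in whole worms mix all tissues, so no difference below is assigned to a tissue.

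The deposited records disagree about which array belongs to which group. Of the 12 columns of the authors' value table, 3 match the scanner file of their own sample and 9 match a scanner file of another group. The groups used here follow the sample record of each scanner file. Under the column labels of the value table, the arrays called maternal here would be mendelian F1, those called mendelian F1 would be non-mendelian F1, and those called non-mendelian F1 would be maternal. Every comparison depends on this choice, which the data did not settle. Array values correlated at 0.957 to 0.989 within groups and at 0.914 to 0.986 between groups. The first principal component held 46.5% of the variance, with paternal replicate 2 at its far end (-115.1).

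The gene overexpressed in the study, gpr-1, encodes a GoLoco protein that, with its near copy gpr-2 and the coiled-coil protein lin-5, anchors dynein at the cell cortex and pulls on the mitotic spindle. High gpr-1 in the zygote can separate the maternal from the paternal chromosomes. The level of gpr-1 was 0.17 ± 0.06 in the paternal group, 0.02 ± 0.09 in the maternal group, 0.14 ± 0.04 in the mendelian F1 and 0.06 ± 0.07 in the non-mendelian F1. The levels of gpr-2 were -0.09 ± 0.05, -0.20 ± 0.05, -0.07 ± 0.09 and -0.22 ± 0.02, and those of lin-5 were 0.85 ± 0.06, 0.79 ± 0.04, 0.92 ± 0.04 and 0.85 ± 0.06, in the same order. None of the 3 genes was called in any comparison. A probe for the native gpr-1 transcript need not detect a recoded transgene, so its steady level checks nothing. The trafficking gene unc-119, often used as a transformation marker, stood at -1.55 ± 0.05, -1.80 ± 0.15, -2.25 ± 0.11 and -2.48 ± 0.13. It fell in the non-mendelian F1 against the paternal group (-0.93 ± 0.12, adjusted p = 0.00439, and adjusted p = 0.00692 with the slide as a block). It also fell in the mendelian F1 against the maternal group (-0.45 ± 0.12, adjusted p = 0.037, but 0.163 with the slide as a block).

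Genes that differed between the parental strains included defence and cuticle genes. Lysozymes such as ilys-3 digest bacterial cell walls, C-type lectins such as clec-13 bind sugars on microbes, and col-49 and col-17 encode collagens of the cuticle. Among genes with the opposite difference, mtm-9 encodes a myotubularin-family protein of endocytic traffic, ztf-28 a zinc finger protein and amt-1 an ammonium transporter. Of 20348 genes tested, 1611 differed between the maternal and paternal groups, 1264 higher and 347 lower in the maternal group. Quantile normalization gave 1104 higher and 857 lower, so the share of rises depended on scaling. The count was 1189 with the slide as a block, 363 with normexp correction, 386 with only these 2 groups in the fit, 335 on the slide of 8 arrays, and between 665 (without maternal replicate 2) and 2490 (without paternal replicate 3) when 1 sample was left out. Genes of unknown function among the rises were F57G8.7 (10.41 ± 0.97, adjusted p = 0.000349), F59C6.18 (9.73 ± 0.74, adjusted p = 0.000104), K03D3.2 (9.67 ± 1.03, adjusted p = 0.000602), F58E2.2 (9.46 ± 0.58, adjusted p = 2.89e-05) and Y49G5A.1 (7.95 ± 0.59, adjusted p = 9.58e-05). F57G8.7, K03D3.2, F58E2.2 and clec-13 were above background on only 1 of the 3 paternal arrays and ilys-3 on 2, so their differences are estimates from mostly dim signals and not exact folds. Both clec-13 (6.98 ± 1.02, adjusted p = 0.00333) and ilys-3 (6.65 ± 0.65, adjusted p = 0.000409) rose. Where no array of a group lay above background, only a minimum fold is given, with the dim signals raised to the lowest signal seen above background on each array. On that scale col-49 rose at least 168-fold (adjusted p = 0.0188), C36C5.15 at least 130-fold (adjusted p = 1.07e-05) and col-17 at least 100-fold (adjusted p = 0.0122) over the paternal group.

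The strongest fall in the maternal group was mtm-9, from 0.43 ± 0.08 to -5.37 ± 0.27 (-5.80 ± 0.16, adjusted p = 2.04e-07). Of its 3 probes, 2 fell, and the gene spans 3743576 to 3749433 on chromosome V in build ce6 (WS190). Y48E1B.8 (-5.0 ± 0.67, adjusted p = 0.00222) and ztf-28 (-4.65 ± 0.25, adjusted p = 1.68e-05) fell too. The F-box gene fbxa-6 fell at least 14.6-fold (adjusted p = 0.00114), F28A10.5 at least 8.51-fold (adjusted p = 0.013), amt-1 at least 8.48-fold (adjusted p = 0.00698) and linc-72 at least 5.72-fold (adjusted p = 0.00629). Smaller falls were those of nssp-46 (-2.89 ± 0.39, adjusted p = 0.00222), nas-2 (-2.60 ± 0.50, adjusted p = 0.0128, from a probe shared with another gene) and clec-245 (-2.38 ± 0.52, adjusted p = 0.0236). Nas-2 and clec-245 were above background on 1 of 3 maternal arrays and Y48E1B.8 on 2. Under the column labels of the value table the falls of mtm-9 (0.009) and fbxa-6 (-0.012) vanished, while Y48E1B.8 (-5.031) and ztf-28 (-4.54) still fell. Once the slide entered as a block, all 20 genes named by size kept their direction and stayed called, for example F57G8.7 (10.34), ilys-3 (6.72) and mtm-9 (-5.73). On the slide of 8 arrays alone mtm-9 differed by -5.78, but the rule of choice fixed the direction of all 20 there.

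**Figure D1:**
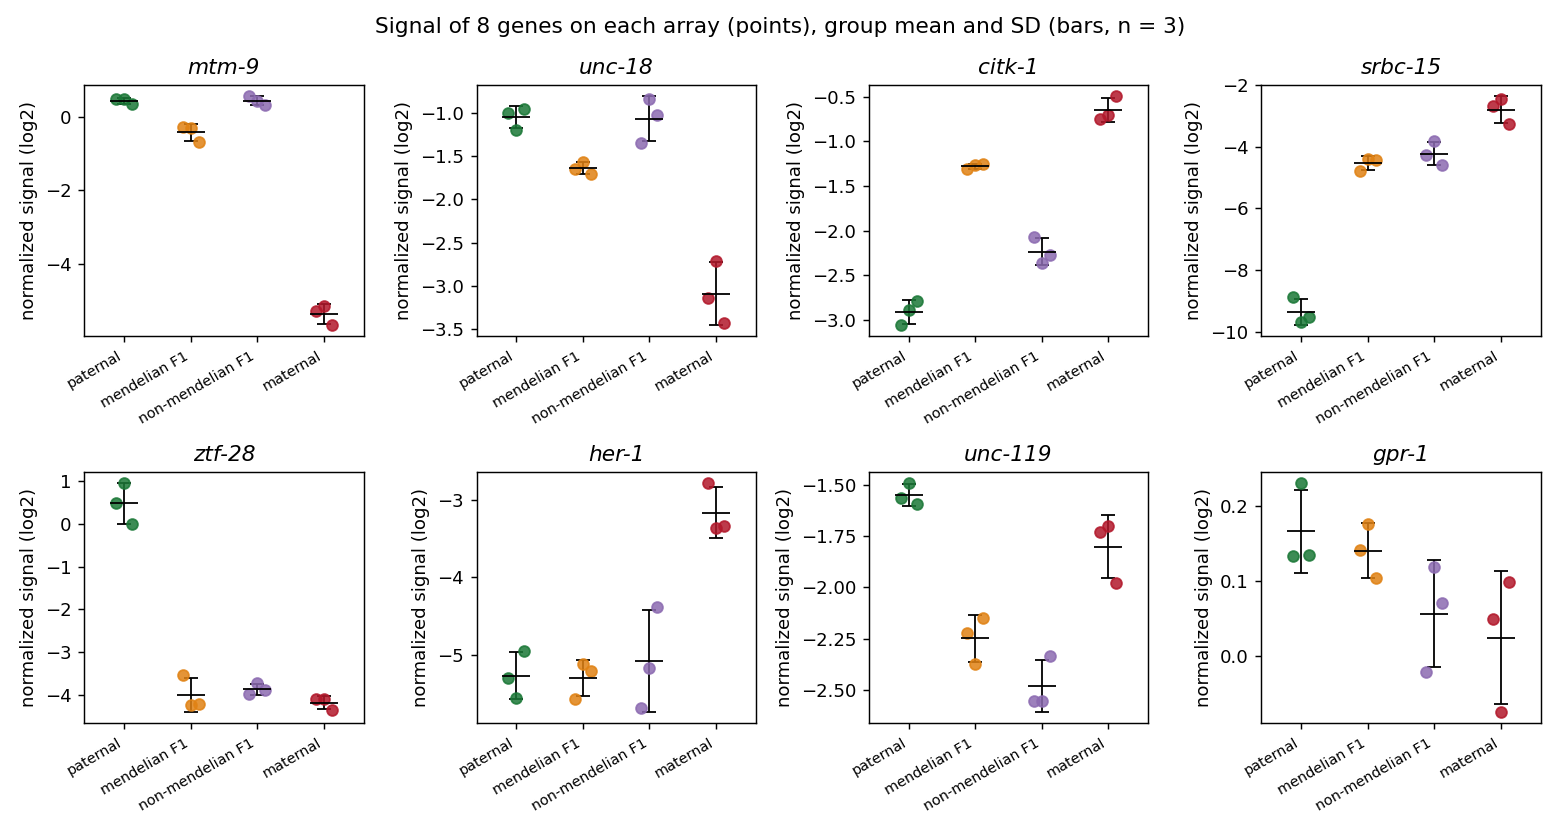
Log2 signal relative to the 75th percentile (y axis) on each of the 12 arrays by group (x axis) for genes named in the text. Levels such as that of mtm-9 separate the maternal arrays from the rest, while gpr-1 stays level.

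Sets of neuropeptides and immune effectors stood higher in the maternal group with the preset correlation, but not with an estimated one. Neuropeptides such as flp-34 and nlp-2 carry signals between neurons, nlp-25, nlp-34 and cnc-6 encode antimicrobial peptides, and pals genes form the response to intracellular pathogens. Of 51 neuropeptide genes, 28 rose, 0 fell and 23 were not called in the maternal against the paternal group, and 37 rose when adjusted over the list alone. Their median was 0.67 (limma camera adjusted p = 1.93e-14 with a preset correlation between genes, adjusted p = 0.5 with an estimated correlation). Examples were flp-26 (0.98, adjusted p = 0.00191), flp-34 (1.45, adjusted p = 0.00237), nlp-2 (1.27, adjusted p = 0.00247) and flp-20 (0.98, adjusted p = 0.00263). Of 63 antimicrobial genes, 26 rose, 0 fell and 37 were not called, with 35 higher when adjusted over the list alone. Their median was 1.11 (adjusted p = 1.27e-13, adjusted p = 0.5 with an estimated correlation), led by nlp-25 (4.51, adjusted p = 6.93e-05), nlp-34 (4.99, adjusted p = 0.000251) and cnc-6 (5.25, adjusted p = 0.000442). The intracellular pathogen response had 16 of 30 genes higher, 0 lower and 14 not called, with 20 higher over the list alone (median 1.02, adjusted p = 3.37e-11, adjusted p = 0.5 with an estimated correlation). Among its members pals-32 rose by 5.32 (adjusted p = 3e-05), pals-39 by 4.03 (adjusted p = 0.00318) and pals-1 by 0.90 (adjusted p = 0.00424). Nlp-25 and pals-39 were above background on 1 of 3 paternal arrays and pals-32 on 2, so these differences are not exact folds. In a fit with the slide as a block the medians of neuropeptides, antimicrobial genes and the intracellular pathogen response were 0.59, 1.05 and 1.0, and on the slide of 8 arrays 0.54, 0.88 and 0.87.

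Sperm genes stood higher in the maternal group as sets with the preset correlation only, and few single genes were called. Major sperm proteins drive the crawling of sperm and signal to oocytes. Of 35 major sperm protein genes 0 were called over all genes, while 35 were higher when adjusted over the list alone (median 3.25, adjusted p = 1.66e-11, adjusted p = 0.5 with an estimated correlation). The estimated correlation between these genes was 1, and 11 of the 35 have a shared probe, so they count as about 1 measurement per array. Of 56 other sperm genes 2 rose, ssp-28 (1.21, adjusted p = 0.0017) and spe-47 (1.29, adjusted p = 0.00972), 0 fell and 54 were not called, with 35 higher over the list alone (median 1.68, adjusted p = 3.83e-08, adjusted p = 0.5 with an estimated correlation). With the slide as a block these medians were 2.69 and 1.38, and on the slide of 8 arrays 2.12 and 1.19. The mean of the major sperm proteins was 2.86, -2.29 and -0.75 on the 3 paternal arrays against 2.79 to 3.50 on the maternal arrays, so part of this difference rested on unequal paternal samples (median 2.12 without paternal replicate 2).

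Structural and metabolic sets stood higher in the maternal group with the preset correlation only. Collagens build the cuticle, glutathione transferases such as gst-14 and cytochromes such as cyp-33C8 clear toxins, and tnt-4 encodes a pharyngeal troponin. Cuticle collagens had 19 of 169 genes higher, 0 lower and 150 not called, with 22 higher over the list alone, including col-104 (3.38, adjusted p = 0.00124), col-176 (3.35, adjusted p = 0.00222) and col-37 (2.09, adjusted p = 0.00245). Their median was 0.45 (adjusted p = 3.06e-06, adjusted p = 0.75 with an estimated correlation), or 0.31 with the slide as a block and 0.15 on the slide of 8 arrays. Pharynx genes had 2 of 22 higher, tnt-4 (0.93, adjusted p = 0.0382) and abu-15 (2.74, adjusted p = 0.049, above background on 2 of 3 paternal arrays), with 9 over the list alone (median 0.75, adjusted p = 3.06e-05, adjusted p = 0.5 with an estimated correlation). Neither tnt-4 (adjusted p = 0.0596) nor abu-15 (adjusted p = 0.0904) stayed called with the slide as a block. Detoxification genes had 23 of 168 higher, 1 lower and 144 not called, with 34 higher and 1 lower over the list alone, among them gst-14 (1.56, adjusted p = 0.000404) and cyp-33C8 (1.98, adjusted p = 0.00189). Their median was 0.27 (adjusted p = 0.00112, adjusted p = 0.75 with an estimated correlation). Intestine genes had 3 of 29 higher, 1 lower and 25 not called, with 9 higher and 1 lower over the list alone (median 0.23, adjusted p = 0.049, adjusted p = 0.75 with an estimated correlation). The proteases cpr-1 (1.4, adjusted p = 0.00455) and cpr-5 (-1.39, adjusted p = 0.0384, but 0.0725 with the slide as a block) moved in opposite directions. Once the slide entered as a block, the medians of pharynx, detoxification and intestine genes were 0.63, 0.27 and 0.13, and on the slide of 8 arrays 0.62, 0.17 and 0.19.

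The sets that stood lower in the maternal group with the preset correlation shifted little, and none passed with an estimated one. Oxidative phosphorylation supplies ATP in mitochondria, cdk-4 starts the cell cycle, nrde-3 carries small RNAs into the nucleus and xol-1 promotes male fate. Oxidative phosphorylation had 1 of 40 genes lower, ucr-2.2 (-0.62, adjusted p = 0.0486), with 39 not called and 0 over the list alone (median -0.21, adjusted p = 1.77e-06, adjusted p = 0.5 with an estimated correlation). Cell cycle genes had 1 of 44 lower, cdk-4 (-0.67, adjusted p = 0.0259), with 43 not called and 0 over the list alone (median -0.13, adjusted p = 1.52e-05, adjusted p = 0.5 with an estimated correlation). Early embryonic genes had 1 of 45 higher, sdz-35 (2.19, adjusted p = 0.00124, above background on 1 of 3 paternal arrays), and 2 lower, sdz-37 (-0.71, adjusted p = 0.0271) and ceh-51 (-1.13, adjusted p = 0.0439), with the same counts over the list alone (median -0.29, adjusted p = 0.00112, adjusted p = 0.63 with an estimated correlation). Oocyte genes (median -0.14, adjusted p = 0.00122, adjusted p = 0.5 with an estimated correlation) and genes of germline mitosis and meiosis (median -0.10, adjusted p = 0.0056, adjusted p = 0.5 with an estimated correlation) had 0 of 31 and 0 of 41 members called, and 0 over the list alone. Dosage compensation and sex determination had 1 of 24 higher, the male-fate gene her-1 (2.12, adjusted p = 0.00376), 1 lower, xol-1 (-0.80, adjusted p = 0.00931), and 22 not called, with 2 higher and 3 lower over the list alone (median -0.10, adjusted p = 0.0107, adjusted p = 0.5 with an estimated correlation). Small RNA silencing had 1 of 41 higher, alg-3 (2.73, adjusted p = 0.048, above background on 1 of 3 paternal arrays), and 1 lower, nrde-3 (-0.78, adjusted p = 0.0178), with 39 not called and 1 lower over the list alone (median -0.07, adjusted p = 0.0191, adjusted p = 0.5 with an estimated correlation). Only alg-3 of these genes lost its call with the slide as a block (adjusted p = 0.0791). In a fit with the slide as a block the medians, in the order of this paragraph, were -0.23, -0.10, -0.31, -0.10, -0.09, -0.16 and -0.07, and on the slide of 8 arrays -0.25, -0.06, -0.21, -0.11, -0.05, -0.16 and -0.04.

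Of 31 lists tested between the parental groups, 16 passed with the preset correlation, 9 higher and 7 lower, and 0 passed with an estimated correlation. The median shifts and camera adjusted p-values of the other lists were -0.10 and 0.0611 for the spindle pulling force complex, 0.28 and 0.0611 for body wall muscle, 0.40 and 0.0534 for pan-neuronal genes, and 0.25 and 0.0996 for insulin and dauer signalling. They were -0.16 and 0.334 for vitellogenins, 0.70 and 0.334 for male neurons, 0.21 and 0.334 for fatty acid metabolism, 0.01 and 0.424 for the cytosolic ribosome, and 0.01 and 0.567 for the unfolded protein response. For neurotransmitter identity they were 0.07 and 0.63, for histones 0.28 and 0.63, for larval moult 0.04 and 0.728, for chemoreceptors 0.02 and 0.728, for oxidative stress defence -0.06 and 0.88, and for heat shock -0.12 and 0.923.

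X-linked genes made up most of the genes that fell in the maternal group. *C. elegans* hermaphrodites carry 2 X chromosomes whose expression is lowered by dosage compensation. The X-linked gene unc-18 encodes a syntaxin-binding protein needed for synaptic vesicle release. Of 331 called falls with a position, 195 lay on the X chromosome (58.9%, against 15.1% of the genes tested; odds ratio 8.59, Fisher p = 1.68e-76), while 125 of 1208 called rises were X-linked too (10.3%, odds ratio 0.635). The median of these X-linked falls was -0.80, and they included W06D11.1 (-1.69 ± 0.11, adjusted p = 4.86e-05), lido-5 (-1.77 ± 0.16, adjusted p = 0.000243), unc-18 (-2.04 ± 0.19, adjusted p = 0.000363) and srv-7 (-1.84 ± 0.18, adjusted p = 0.000383). Mean levels of the 195 genes were -1.93 ± 0.07 in the paternal group, -2.83 ± 0.01 in the maternal group, -2.02 ± 0.04 in the mendelian F1 and -2.2 ± 0.10 in the non-mendelian F1. Over all 2903 X-linked genes the median was -0.04, below each of 10000 lists of genes not placed on the X chromosome, matched in number and mean expression, but the medians of chromosome I (-0.04) and chromosome III (-0.02) lay close to it. Among the called rises, 415 lay on chromosome V (34.4%, odds ratio 2.07, Fisher p = 3.4e-28). Neighbouring genes and shared regulation make these Fisher p-values too small.

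The 2 F1 groups differed in many of the same genes as their parents. C36C5.15 and its neighbour C36C5.14 are of unknown function, fip-1 belongs to the family of fungus-induced peptides, icmt-1 encodes a methyltransferase of prenylated proteins, and the insulin-like peptide ins-6 acts in dauer recovery. Of 20348 genes, 1042 differed, 997 higher and 45 lower in the non-mendelian than in the mendelian F1. With the slide as a block 669 differed (629 higher, 40 lower), quantile normalization gave 422 higher and 144 lower, normexp correction 124 genes, and leaving out 1 sample 210 (mendelian F1 replicate 1) to 2007 (paternal replicate 2). The median of all genes was 0.17 with the scaling used and -0.10 with quantile normalization, so scaling accounts for part of the excess of rises. Under the column labels of the value table, genes such as F57G8.7 (-10.896) and ins-6 (2.039) turned direction between the F1 groups. The values below follow the scanner files. F57G8.7 rose at least 2190-fold (adjusted p = 0.000501), F58E2.2 at least 503-fold (adjusted p = 6.64e-05), C36C5.15 at least 376-fold (adjusted p = 8.24e-06), C36C5.14 at least 146-fold (adjusted p = 8.4e-05) and fip-1 at least 53.7-fold (adjusted p = 0.00293). Also higher were F59C6.18 (9.38 ± 0.74, adjusted p = 0.000264), K03D3.2 (8.90 ± 1.03, adjusted p = 0.00213), Y49G5A.1 (6.28 ± 0.59, adjusted p = 0.000727), M199.9 (5.90 ± 0.32, adjusted p = 2.95e-05) and icmt-1 (5.58 ± 1.22, adjusted p = 0.0334, above background on 2 of 3 mendelian arrays).

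Among the genes lower in the non-mendelian F1, ins-6 fell from -2.98 ± 0.07 to -5.38 ± 0.15 (-2.40 ± 0.15, adjusted p = 5.66e-05). Y48E1B.8 (-4.24 ± 0.67, adjusted p = 0.0107), Y69A2AR.25 (-3.05 ± 0.34, adjusted p = 0.00173), Y69A2AR.12 (-3.01 ± 0.29, adjusted p = 0.000796) and the protease gene nas-3 (-2.66 ± 0.51, adjusted p = 0.0212) fell as well. Y69A2AR.25 and nas-3 were above background on 2 of 3 non-mendelian arrays and Y69A2AR.12 on 1. Minimum falls were 8.6-fold for clec-100 (adjusted p = 0.0131), 7.41-fold for F57G4.11 (adjusted p = 0.0129), 5.89-fold for Y19D10A.6 (adjusted p = 0.0253), 5.4-fold for amt-1 (adjusted p = 0.0312) and 4.61-fold for nas-2 (adjusted p = 0.037). The probes of Y19D10A.6 and nas-2 are shared with other genes. Ins-6 differed by -2.46 on the slide of 8 arrays and -2.30 on the slide of 4. The rule of choice fixed the direction of all 20 genes named by size on each slide. Once the slide entered as a block, 17 of 20 stayed called, ins-6 at -2.43 (adjusted p = 0.000224), while icmt-1 (adjusted p = 0.0568), amt-1 (adjusted p = 0.0568) and nas-2 (adjusted p = 0.054) did not. Of the genes higher in the maternal than in the paternal group, 434 were also higher in the non-mendelian than in the mendelian F1 (61.9 expected if independent), and 24 were lower in both comparisons (0.8 expected). These comparisons share no array, but they share the estimate of the spread of each gene, so the counts expected if independent are only a guide.

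Sperm, cuticle and antimicrobial sets stood higher in the non-mendelian than in the mendelian F1 with the preset correlation, though not with an estimated one. Spe genes act in sperm development, and the moulting genes noah-2 and ptr-4 shape the new cuticle. Of 56 other sperm genes 8 rose, including ssp-32 (at least 7.33-fold, adjusted p = 0.0101, shared probe), spe-57 (at least 7-fold, adjusted p = 0.0121) and spe-46 (2.46, adjusted p = 0.0227), 0 fell and 48 were not called, with 40 higher over the list alone (median 2.17, adjusted p = 4.36e-09, adjusted p = 0.68 with an estimated correlation). Major sperm proteins had 0 of 35 called and 0 over the list alone (median 2.39, adjusted p = 5.48e-06, adjusted p = 0.76 with an estimated correlation). Collagens had 16 of 169 higher, 0 lower and 153 not called, with 18 over the list alone (median 0.67, adjusted p = 1.75e-07, adjusted p = 0.76 with an estimated correlation), led by col-176 (3.48, adjusted p = 0.00383). Antimicrobial genes had 18 of 63 higher, 2 lower and 43 not called, with 24 higher and 4 lower over the list alone (median 0.74, adjusted p = 0.000569, adjusted p = 0.76 with an estimated correlation), including nlp-25 (3.28, adjusted p = 0.000796, above background on 2 of 3 mendelian arrays) and nlp-34 (3.33, adjusted p = 0.00412). Neuropeptides had 6 of 51 higher, 0 lower and 45 not called, with 9 over the list alone (median 0.39, adjusted p = 5.48e-06, adjusted p = 0.76 with an estimated correlation), among them flp-34 (1.4, adjusted p = 0.00628) and nlp-4 (1.82, adjusted p = 0.0186). In a fit with the slide as a block the medians of other sperm genes, major sperm proteins, collagens, antimicrobial genes and neuropeptides were 1.79, 1.84, 0.52, 0.74 and 0.35. They were 2.03, 2.24, 1.0, 1.19 and 0.36 on the slide of 8 arrays and 1.87, 2.0, 0.25, 0.61 and 0.29 on the slide of 4.

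Larval moult genes had 2 of 25 higher, noah-2 (1.37, adjusted p = 0.041) and ptr-4 (2.04, adjusted p = 0.044, above background on 2 of 3 mendelian arrays), 0 lower and 23 not called, with 9 over the list alone (median 0.69, adjusted p = 0.00196, adjusted p = 0.76 with an estimated correlation). Pharynx genes had 3 of 22 higher, phat-2 (1.98, adjusted p = 0.0131), the pharyngeal regulator ceh-22 (1.34, adjusted p = 0.0301) and abu-14 (2.59, adjusted p = 0.0356), with 19 not called and 5 higher over the list alone (median 0.63, adjusted p = 0.000409, adjusted p = 0.76 with an estimated correlation). With the slide as a block phat-2 alone of these 5 genes stayed called (adjusted p = 0.0212), and the list medians were 0.54 and 0.57. On the slide of 8 arrays they were 0.85 and 0.54, and on the slide of 4 arrays 0.51 and 0.52. The 7 other lists that passed with the preset correlation had 0 members called. Body wall muscle (median 0.35, adjusted p = 0.00737) and pan-neuronal genes (0.42, adjusted p = 0.0145) stood higher. Genes of germline mitosis and meiosis (-0.13, adjusted p = 1.75e-07), oocytes (-0.16, adjusted p = 5.28e-06), the cell cycle (-0.11, adjusted p = 1.75e-07), small RNA silencing (-0.10, adjusted p = 0.000168) and oxidative phosphorylation (-0.08, adjusted p = 1.64e-05) stood lower. For body wall muscle, pan-neuronal genes and oxidative phosphorylation the adjusted p = 0.76 with an estimated correlation, and for the other 4 it was 0.38. In that order of 7 lists the medians were 0.26, 0.32, -0.12, -0.12, -0.08, -0.08 and -0.13 with the slide as a block, 0.32, 0.35, -0.13, -0.12, -0.18, -0.12 and -0.02 on the slide of 8 arrays, and 0.35, 0.33, -0.14, -0.09, -0.04, -0.06 and -0.20 on the slide of 4. The intracellular pathogen response did not pass (0.29, adjusted p = 0.0522). In all, 14 lists passed and 0 did with an estimated correlation, where the lowest adjusted p was 0.38.

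**Figure D2:**
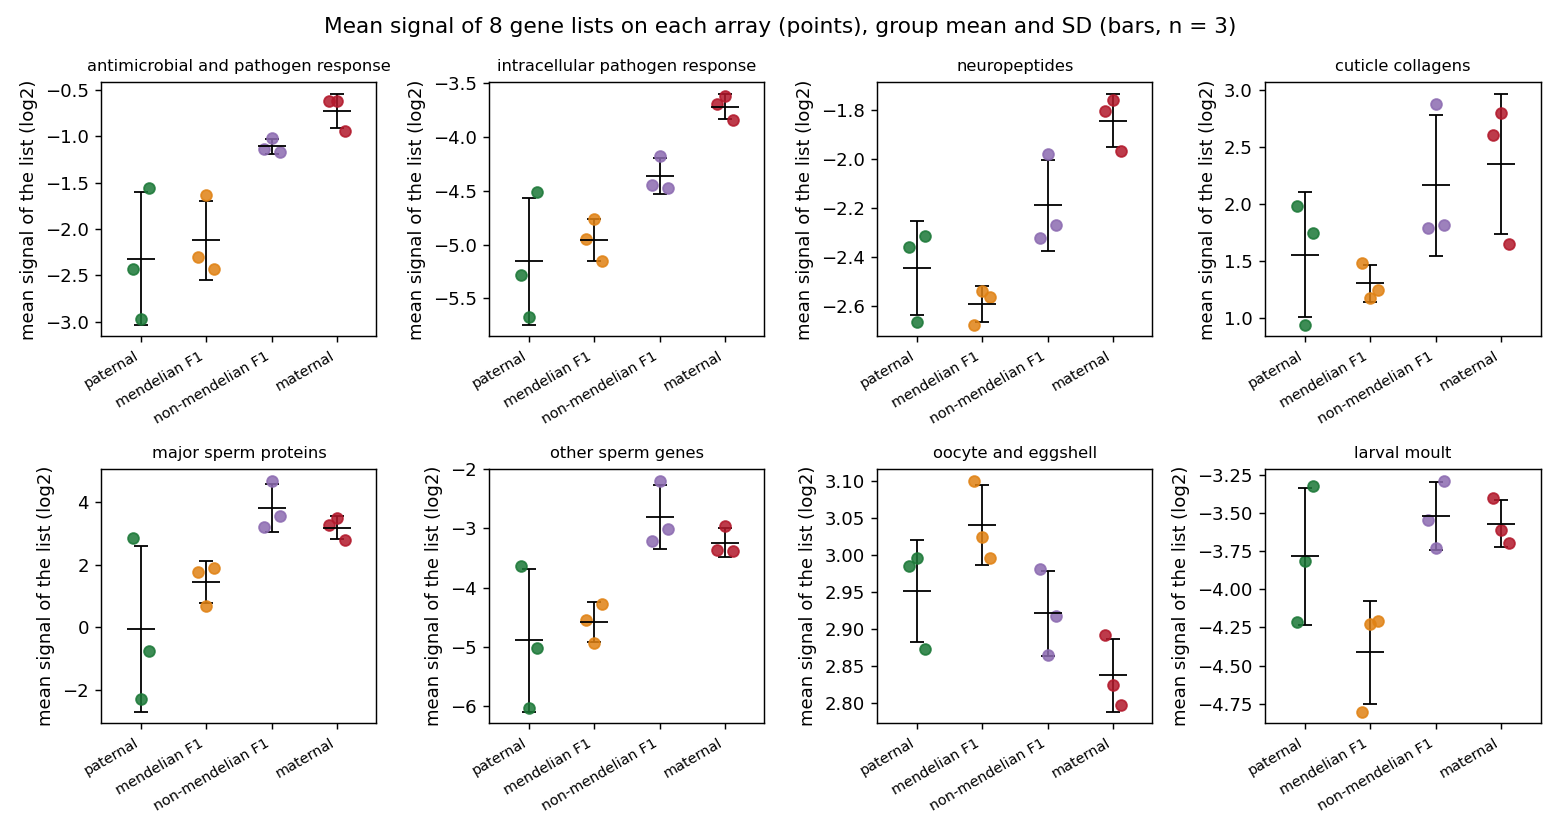
Mean log2 signal of gene lists relative to the 75th percentile (y axis) on each array, by group (x axis). The paternal arrays scatter most for the sperm lists, while the antimicrobial list lies higher on the maternal and non-mendelian arrays than on the paternal and mendelian arrays, which overlap.

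Placing each F1 sample between its parents asks which parental strain its expression resembles. On this axis the paternal level is -0.5, the mean of the parents 0 and the maternal level 0.5. Over the 1611 genes that differed between the parents, the mendelian F1 lay at -0.37 ± 0.05 (-0.418 to -0.33) and the non-mendelian F1 at 0.25 ± 0.09 (0.2 to 0.352). The exact permutation p was 0.1, the smallest possible with 3 samples per group. Over the 1264 called rises the positions were -0.38 ± 0.05 and 0.28 ± 0.09. The 195 X-linked falls placed both F1 groups on the paternal side (-0.39 ± 0.04 and -0.16 ± 0.10), and the 152 other falls put them at -0.12 ± 0.04 and 0.12 ± 0.05. The parental arrays both define this axis and selected its genes, so noise in them can shift every position. Per the labels the non-mendelian F1 carried the paternal genotype in body wall muscle, intestine and germline, yet it lay on the maternal side over all 1611 genes. The reason was not tested. Under the column labels of the value table, the arrays called mendelian F1 here would be non-mendelian F1. The maternal arrays would change too, and positions under those labels were not computed.

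**Figure D3:**
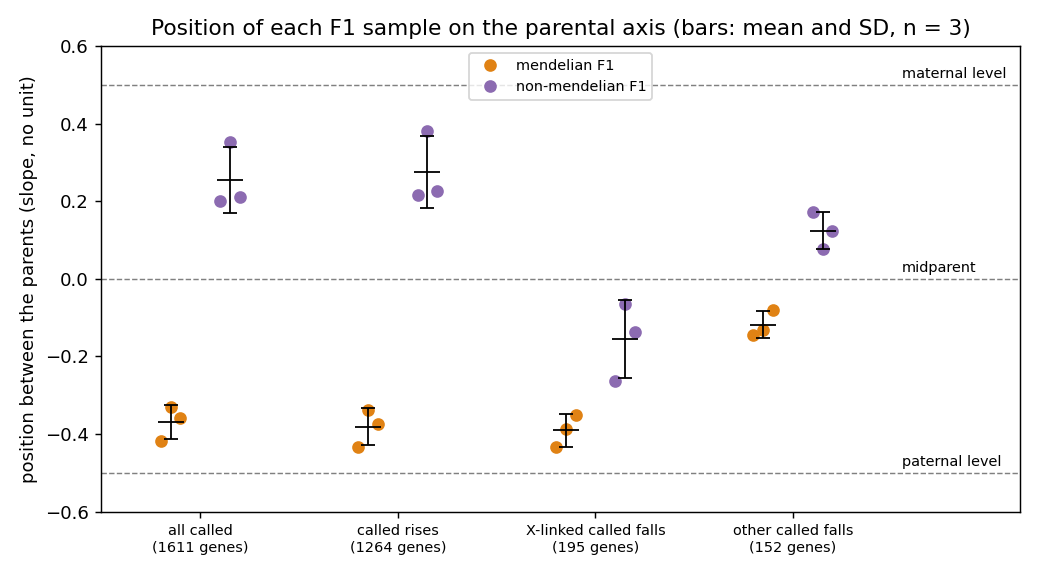
Position of each F1 sample on the parental axis (y axis, no unit) for 4 gene sets (x axis), with dashed lines at the paternal and maternal levels. The non-mendelian F1 lies nearer the maternal level for rises but not for X-linked falls.

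Few genes were called between the mendelian F1 and the paternal group. Among them, citk-1 encodes a citron kinase relative, srg-31 a chemoreceptor and srbc-15 a chemoreceptor pseudogene. Of 20348 genes 8 were called by limma, 6 higher and 2 lower, with 1913 at an unadjusted p under 0.05 (median of all genes -0.12). Once the slide entered as a block, 3 were called. Srbc-15 rose at least 28.2-fold (adjusted p = 0.000149) and citk-1 by 1.64 ± 0.12 (adjusted p = 0.000991), while ztf-28 fell from 0.47 ± 0.47 to -3.99 ± 0.40 (-4.46 ± 0.25, adjusted p = 0.000149). These 3 genes stayed called with the slide as a block, citk-1 at 1.61 and ztf-28 at -4.56. Y19D10A.16 (1.05 ± 0.12, adjusted p = 0.0258), srg-31 (2.69 ± 0.31, adjusted p = 0.0262), C09G5.7 (1.31 ± 0.15, adjusted p = 0.0262) and C17B7.12 (-2.37 ± 0.30, adjusted p = 0.0332) were called without that block only. Of the falls that were not called, those with the lowest p were in 3 genes: Y46E12A.2 differed by -1.96 (adjusted p = 0.0584), Y47G7B.2 by -1.03 (adjusted p = 0.0808) and K01D12.9 by -1.99 (adjusted p = 0.0808, above background on 1 of 3 mendelian arrays). The level of citk-1 was -2.91 ± 0.14 in the paternal group and -0.65 in the maternal group, with the mendelian F1 between them (-1.28 ± 0.03).

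Of 31 lists, 13 passed between the mendelian F1 and the paternal group with the preset correlation and 0 with an estimated correlation. Major sperm proteins had 0 of 35 called and 0 over the list alone (median 1.5, adjusted p = 1.48e-13, adjusted p = 0.72 with an estimated correlation), at 0.84 on the slide of 8 arrays, 3.53 on the slide of 4 and 2.05 with the slide as a block, but 0.38 without paternal replicate 2. The mean of the list on paternal replicate 1 (2.86) lay above that on every mendelian array (0.67 to 1.89). Larval moult genes, such as ptr-4 and noah-2, had 0 of 25 called and 0 over the list alone (median -0.46, adjusted p = 0.000262, adjusted p = 0.72 with an estimated correlation), at -0.44, -0.42 and -0.44. The antimicrobial list changed sign between slides (-0.54 on the slide of 8 arrays, 0.79 on the slide of 4, 0.15 with the slide as a block), with 0 of 63 genes called and 1 higher over the list alone (median 0.08, adjusted p = 0.00173, adjusted p = 0.95 with an estimated correlation).

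Between the mendelian F1 and the maternal group, the genes that differed included neuropeptides and antimicrobial genes. Cpr-5 encodes a cathepsin B protease, rab-3 and sbt-1 act in neurosecretion, and ins-20 and ins-11 encode insulin-like peptides. Of 20348 genes 2982 differed, 357 higher and 2625 lower in the mendelian F1. In a fit with the slide as a block 875 differed (143 higher, 732 lower), quantile normalization gave 835 higher and 1054 lower, normexp correction 754 genes, and leaving out 1 sample 1030 (maternal replicate 2) to 4197 (paternal replicate 2). The median of all genes was -0.25 with the scaling used and 0.10 with quantile normalization, so the excess of falls depended on scaling. Mtm-9 rose (4.95 ± 0.16, adjusted p = 9.59e-07, with 2 of 3 probes), as did Y48E1B.8 (4.49 ± 0.67, adjusted p = 0.00345), Y69A2AR.12 (2.49 ± 0.29, adjusted p = 0.00102), cpr-5 (2.12 ± 0.35, adjusted p = 0.00491) and clec-100 (at least 6.75-fold, adjusted p = 0.00863). Y48E1B.8 and Y69A2AR.12 were above background on 2 of 3 maternal arrays. F57G8.7 fell at least 2390-fold (adjusted p = 0.000249), F58E2.2 at least 367-fold (adjusted p = 8.61e-05), col-49 at least 230-fold (adjusted p = 0.0107), F59C6.18 by 9.39 ± 0.74 log2 units (adjusted p = 0.000154) and K03D3.2 by 8.57 ± 1.03 (adjusted p = 0.00113). With the slide as a block 9 of these 10 genes stayed called, mtm-9 at 4.81, all but col-49 (adjusted p = 0.0658). On the slide of 8 arrays mtm-9 differed by 4.69. Of the called rises with a position, 199 of 342 were X-linked (58.2%, odds ratio 8.35, Fisher p = 9.48e-77), but so were 427 of 2513 falls (17%, odds ratio 1.18, Fisher p = 0.00449), and the median over all X-linked genes was -0.35. The same maternal arrays entered the comparison of the parental groups, so the X-linked rises are not a separate finding from the X-linked falls there.

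In this comparison 22 of 31 lists passed with the preset correlation, 8 higher and 14 lower, and 0 with an estimated correlation. Neuropeptides had 36 of 51 lower, 0 higher and 15 not called, with 42 lower over the list alone (median -0.78, adjusted p = 6.74e-14, adjusted p = 0.41 with an estimated correlation), led by flp-34 (-1.89, adjusted p = 0.000634) and flp-26 (-1.08, adjusted p = 0.00106). Pan-neuronal genes had 14 of 28 lower, 1 higher and 13 not called, with 18 lower and 1 higher over the list alone (median -0.64, adjusted p = 0.00193, adjusted p = 0.57 with an estimated correlation). The exception was unc-18, which rose (1.45, adjusted p = 0.00189), while sbt-1 (-0.80, adjusted p = 0.0067) and rab-3 (-0.76, adjusted p = 0.00706) fell. Antimicrobial genes had 26 of 63 lower, 0 higher and 37 not called, with 37 lower over the list alone (median -1.27, adjusted p = 2.41e-06, adjusted p = 0.57 with an estimated correlation). Insulin and dauer signalling had 13 of 44 lower, 2 higher and 29 not called, with 22 lower and 4 higher over the list alone (median -0.59, adjusted p = 0.0147, adjusted p = 0.57 with an estimated correlation), with ins-6 higher (1.55, adjusted p = 0.00048) and ins-20 (at least 19.1-fold, adjusted p = 0.00135) and ins-11 (at least 20.4-fold, adjusted p = 0.0017) lower. Of the spindle pulling force complex 1 of 11 genes rose, rgs-7 (0.63, adjusted p = 0.0343, but 0.177 with the slide as a block), and 1 did over the list alone (median 0.12, adjusted p = 0.0352, adjusted p = 0.29 with an estimated correlation). Once the slide entered as a block, the medians of these 5 lists were -0.68, -0.54, -1.07, -0.44 and 0.11, and on the slide of 8 arrays -0.74, -0.64, -1.41, -0.50 and 0.08.

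Genes that differed between the non-mendelian F1 and the paternal group included the antimicrobial genes nlp-25 and ilys-3, the sperm transporter snf-10 and the protease gene nas-3. Of 20348 genes 596 differed, 544 higher and 52 lower in the non-mendelian F1. In a fit with the slide as a block 1288 differed (1205 higher, 83 lower), quantile normalization gave 794 higher and 237 lower, normexp correction 96 genes, and leaving out 1 sample 157 (non-mendelian F1 replicate 2) to 1254 (paternal replicate 1). F57G8.7 (10.28 ± 0.97, adjusted p = 0.000715), K03D3.2 (9.99 ± 1.03, adjusted p = 0.00106), F58E2.2 (9.91 ± 0.58, adjusted p = 3.24e-05) and F59C6.18 (9.72 ± 0.74, adjusted p = 0.000179) rose, and C36C5.15 rose at least 327-fold (adjusted p = 9.66e-06). F57G8.7, K03D3.2 and F58E2.2 were above background on 1 of 3 paternal arrays, so these 3 differences are not exact folds. Y48E1B.8 (-4.76 ± 0.67, adjusted p = 0.0066), ztf-28 (-4.33 ± 0.25, adjusted p = 3.24e-05) and nas-3 (-3.44 ± 0.51, adjusted p = 0.00864, above background on 2 of 3 non-mendelian arrays) fell, with Y19D10A.6 at least 12.2-fold (adjusted p = 0.0072, shared probe) and amt-1 at least 10.8-fold lower (adjusted p = 0.0102). All 10 genes stayed called with the slide as a block, where the differences were the same because both groups had 2 arrays on the first slide and 1 on the second. F57G8.7 differed by 9.70 on the slide of 8 arrays and 11.45 on the slide of 4, and ztf-28 by -4.04 and -4.92.

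Between the non-mendelian F1 and the paternal group 11 of 31 lists passed with the preset correlation and 0 with an estimated correlation. Other sperm genes had 8 of 56 higher, including spe-47 (1.39, adjusted p = 0.0162) and snf-10 (at least 5.09-fold, adjusted p = 0.0389, above background on 2 of 3 non-mendelian arrays), 0 lower and 48 not called, with 38 over the list alone (median 2.48, adjusted p = 1.74e-19, adjusted p = 0.74 with an estimated correlation). Major sperm proteins had 0 of 35 called and 35 over the list alone (median 3.87, adjusted p = 1.06e-23, adjusted p = 0.74 with an estimated correlation). These 35 genes moved together, and their mean was unequal on the 3 paternal arrays (2.86, -2.29 and -0.75). Antimicrobial genes had 16 of 63 higher, among them nlp-25 (3.22, adjusted p = 0.000857, above background on 1 of 3 paternal arrays) and ilys-3 (5.35, adjusted p = 0.00288, on 2 of 3), 0 lower and 47 not called, with 25 over the list alone (median 0.80, adjusted p = 1.46e-11, adjusted p = 0.74 with an estimated correlation). The medians of these 3 lists were 2.11, 3.07 and 0.60 on the slide of 8 arrays and 2.90, 5.52 and 1.4 on the slide of 4, and unchanged with the slide as a block.

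Between the non-mendelian F1 and the maternal group 85 genes were called. Of those named here, unc-18 acts in vesicle release, nmr-1 encodes an NMDA-type glutamate receptor subunit and srv-7 a chemoreceptor. Of 20348 genes tested, 47 were higher and 38 lower in the non-mendelian F1, or 41 and 66 with quantile normalization. With the slide as a block 45 differed (25 higher, 20 lower), with normexp correction 8, and leaving out 1 sample gave 6 (maternal replicate 2) to 144 (paternal replicate 3). Mtm-9 rose (5.81 ± 0.16, adjusted p = 2.03e-07, 2 of 3 probes), as did unc-18 on all 4 of its probes (2.02 ± 0.19, adjusted p = 0.00581), srv-7 (1.76 ± 0.18, adjusted p = 0.00684), nmr-1 (1.66 ± 0.28, adjusted p = 0.0401) and fbxa-6 (at least 18-fold, adjusted p = 0.00885). C54F6.15 (-5.35 ± 0.55, adjusted p = 0.0069, above background on 1 of 3 non-mendelian arrays) and F14F9.6 (-3.26 ± 0.53, adjusted p = 0.0364) fell, with R05H10.7 at least 11.4-fold (adjusted p = 0.0069), F57G4.11 at least 10.4-fold (adjusted p = 0.0214) and ZK662.6 at least 7.67-fold lower (adjusted p = 0.0308). Once the slide entered as a block, 7 of 10 stayed called, mtm-9 at 5.73 and unc-18 at 2.08, but not nmr-1 (adjusted p = 0.0765), F14F9.6 (adjusted p = 0.0892) or ZK662.6 (adjusted p = 0.0765). On the slide of 8 arrays mtm-9 differed by 5.75 and unc-18 by 2.16. The level of unc-18 was -1.07 ± 0.26 in the non-mendelian F1, -1.64 ± 0.07 in the mendelian F1, -1.05 ± 0.13 in the paternal group and -3.09 ± 0.36 in the maternal group. Of 44 called rises with a position, 35 were X-linked (79.5%, odds ratio 22.2, Fisher p = 2.48e-21), as were 2 of 35 falls. This count too rests on the same maternal arrays as the other comparisons with the maternal group and is not a separate finding.

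Against the maternal group 16 of 31 lists passed in the non-mendelian F1 with the preset correlation, 9 with the slide as a block and 0 with an estimated correlation. Neuropeptides had 0 of 51 called, and 11 were lower over the list alone (median -0.38, adjusted p = 5.21e-18, adjusted p = 0.63 with an estimated correlation). The intracellular pathogen response had 1 of 30 lower, pals-1 (-1.03, adjusted p = 0.0194), with 29 not called and 4 lower over the list alone (median -0.57, adjusted p = 1.02e-10, adjusted p = 0.63 with an estimated correlation). Detoxification genes had 0 of 168 called and 2 lower over the list alone (median -0.27, adjusted p = 1.08e-07, adjusted p = 0.8 with an estimated correlation). Pan-neuronal genes had 1 of 28 higher, unc-18, 0 lower and 27 not called, with 1 higher and 1 lower over the list alone (median -0.26, adjusted p = 0.00506, adjusted p = 0.8 with an estimated correlation). In a fit with the slide as a block these 4 medians were -0.31, -0.49, -0.19 and -0.16, and on the slide of 8 arrays -0.32, -0.54, -0.22 and -0.19.

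Few genes were called between both F1 groups together and both parental groups. Odc-1 encodes ornithine decarboxylase, the first enzyme of polyamine synthesis. Of 20348 genes 9 were called, 3 higher and 6 lower in the F1, with 2023 at an unadjusted p under 0.05. With the slide as a block 3 were called. Odc-1 (-0.70 ± 0.09), unc-119 (-0.69 ± 0.09), H11E01.2 (-0.55 ± 0.07) and the pseudogene str-147 (-0.99 ± 0.13, above background on 5 of 6 F1 arrays) fell, each at an adjusted p of 0.0488. The pseudogene srbc-15 was called too (adjusted p = 0.0488), but no paternal array lay above background and both F1 groups (-4.53 and -4.22) lay below the maternal group (-2.80), so its call rests on the paternal group and no size is given. Of these named genes only str-147 (-1.10, adjusted p = 0.0387) stayed called with the slide as a block, against 0.108 for odc-1 and unc-119, 0.133 for H11E01.2 and 0.0771 for srbc-15. On the slide of 8 arrays odc-1 differed by -0.71, unc-119 by -0.61, H11E01.2 by -0.54 and str-147 by -1.01. Not called were F59D12.5 (0.55, adjusted p = 0.075), R02D3.8 (0.30, adjusted p = 0.341), Y37D8A.4 (0.27, adjusted p = 0.399), mtcu-1 (0.22, adjusted p = 0.411), ztf-23 (0.19, adjusted p = 0.471) and F22F4.4 (-0.85, adjusted p = 0.131). Of 31 lists 15 passed with the preset correlation and 0 with an estimated correlation. Major sperm proteins had 0 of 35 called and 0 over the list alone (median 1.07, adjusted p = 2.26e-12, adjusted p = 0.59 with an estimated correlation), at 1.62 with the slide as a block and 0.89 on the slide of 8 arrays, but 0.51 without paternal replicate 2.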

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

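The test of the labels in this part was chosen after the result was seen. Of the 12 columns of the authors' value table, 9 match the scanner file of another group, a signal in data that the comparisons above do not use. A mendelian F1 carries 1 copy from each parent, so few genes should lie far below both parents in it. Under the table's labels 3 genes (mtm-9, unc-18 and fbxa-6) lay at least 4-fold below both parental groups in the mendelian F1 and were called against each, while 0 did under the labels of the scanner files. Counted without the calls there were 5 such genes under the table's labels and 9 under those of the scanner files, which points the other way. Only genes below both parents were counted, so other patterns that bear on the labels were left out. For example, F57G8.7 differed between the mendelian F1 and the maternal group by -11.222 under the scanner labels and 0.104 under the table's. In the same comparison mtm-9 differed by 4.951 and -6.166. The explanation that the value table labels are right and the scanner files sit under other samples therefore stays open (value 3), and no biological explanation was tested for it.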

How the results depend on the processing

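Scaling over all probes, protein-coding genes only and the authors' table under its own labels were chosen after the data were seen. About 49.6% of probes lay well above background on an array, which limits every result on dim genes. Both F1 groups kept their side of the mean of the parents in every setting run for them. Positions ran from -0.404 to -0.292 for the mendelian F1 and from 0.179 to 0.298 for the non-mendelian F1. Positions were not computed from the authors' table under either labelling, on either slide alone, with array weights or with any sample left out. How the axis depends on the labels or on any given sample was therefore not tested. The position of the mendelian F1 was -0.292 with quantile normalization and -0.315 with median centring, against -0.369. Counts of called genes moved far more than directions did, and beyond the smaller numbers of genes or samples in some settings, the causes were not tested. Below, the parental groups means maternal against paternal and the F1 groups means non-mendelian against mendelian F1.

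Normexp background correction called 363 genes between the parental groups, 124 between the F1 groups, 4 in mendelian F1 against paternal, 754 in mendelian F1 against maternal, 96 in non-mendelian F1 against paternal, 8 in non-mendelian F1 against maternal and 2 in F1 against parents. No filter on dim probes gave, in the same order, 530, 222, 3, 776, 175, 6 and 2. Genes well above background on all 12 arrays gave 591 between the F1 groups, 19 in mendelian F1 against paternal, 281 in non-mendelian F1 against paternal and 17 in F1 against parents. The mean of the probes of a gene gave 2 in F1 against parents. A variance trend with robust estimation gave 16 in mendelian F1 against paternal, 945 in non-mendelian F1 against paternal and 17 in F1 against parents. Fitting only the groups compared gave 386 between the parental groups, 1987 between the F1 groups, 2 in mendelian F1 against paternal, 48 in non-mendelian F1 against paternal and 1 in non-mendelian F1 against maternal. Array weights gave 3362 between the F1 groups, 4 in mendelian F1 against paternal, 6144 in mendelian F1 against maternal, 1355 in non-mendelian F1 against maternal and 33 in F1 against parents. Protein-coding genes only gave 130 in non-mendelian F1 against maternal and 14 in F1 against parents.

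Quantile normalization called 566 genes between the F1 groups, 27 in mendelian F1 against paternal, 1889 in mendelian F1 against maternal and 1031 in non-mendelian F1 against paternal. Median centring gave 16 in mendelian F1 against paternal, 1090 in non-mendelian F1 against paternal and 3 in F1 against parents. Scaling by the 75th percentile over all probes gave 22, 1229 and 3 in these same 3 comparisons. The authors' value table, with columns placed by the scanner array they match, gave 543 between the F1 groups, 27 in mendelian F1 against paternal, 1838 in mendelian F1 against maternal and 951 in non-mendelian F1 against paternal. Under its own column labels the authors' value table gave 951 between the parental groups, 1838 between the F1 groups, 1890 in mendelian F1 against paternal, 109 in mendelian F1 against maternal, 27 in non-mendelian F1 against paternal, 543 in non-mendelian F1 against maternal and 94 in F1 against parents.

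The slide as a block gave 669 between the F1 groups, 3 in mendelian F1 against paternal, 875 in mendelian F1 against maternal, 1288 in non-mendelian F1 against paternal, 45 in non-mendelian F1 against maternal and 3 in F1 against parents. Only the slide of 8 arrays gave 335 between the parental groups, 22 between the F1 groups, 0 in mendelian F1 against paternal, 157 in mendelian F1 against maternal, 46 in non-mendelian F1 against paternal, 1 in non-mendelian F1 against maternal and 0 in F1 against parents. On that slide the mendelian F1 had a single array, which was taken to vary like the other groups. Only the slide of 4 arrays gave 0 between the F1 groups, 0 in mendelian F1 against paternal and 0 in non-mendelian F1 against paternal, with single arrays of the paternal group and the non-mendelian F1.

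A replicate block was run because the labels number the samples alike in each group, though the numbers do not pair the samples: 5 of 18 same-numbered pairs correlated above 0.1 (-0.358 to 0.396), and 5 of 12 samples correlated best with their own number. The replicate block gave 456 called genes between the F1 groups, 5 in mendelian F1 against paternal, 234 in non-mendelian F1 against paternal, 22 in non-mendelian F1 against maternal and 2 in F1 against parents. The replicate block with the slide as a block gave 529 between the F1 groups, 4 in mendelian F1 against paternal, 487 in mendelian F1 against maternal, 1334 in non-mendelian F1 against paternal, 13 in non-mendelian F1 against maternal and 2 in F1 against parents. With both blocks gpr-1 (-0.005) and gpr-2 (-0.019) in F1 against parents and msp-37 (0.010), msp-45 (0.067), msp-76 (0.065) and msp-36 (0.069) in mendelian F1 against maternal changed sign.

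With the correlation between genes estimated, 0 gene lists passed in each of the 7 comparisons. A slide block left 9 lists passing in non-mendelian F1 against maternal, against 16.

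Most genes that changed sign had small differences, and all but ceh-22 were not called in the first place. Between the F1 groups these were syd-2 with quantile normalization (-0.003) and with the authors' table placed by matching array (-0.002), lin-5 on the slide of 8 arrays (0.007) and ceh-22 with that table (-0.932, adjusted p = 0.622). In mendelian F1 against paternal they were pals-39 (-0.127) and alg-3 (-0.033) with normexp, gpr-1 with median centring (0.095) and with scaling over all probes (0.137), and on the slide of 8 arrays gpr-2 (-0.045), hsp-16.1 (-0.548), hsp-16.11 (-0.536) and hsp-16.49 (-1.078). On the slide of 4 arrays they were pie-1 (-0.009), swm-1 (0.168), tbg-1 (-0.004) and sid-2 (0.094). In mendelian F1 against maternal dnc-1 changed sign with median centring (0.005) and with scaling over all probes (0.099). In non-mendelian F1 against paternal lin-5 did with quantile normalization (0.010), on the slide of 8 arrays (0.064), with array weights (0.023) and with the authors' table placed by matching array (0.009), and bub-1 did on the slide of 8 arrays (0.002). In non-mendelian F1 against maternal gpr-2 did with scaling over all probes (0.001). In F1 against parents gpr-2 did with normexp (-0.004), with the slide as a block (-0.022) and on the slide of 8 arrays (-0.030), and gpr-1 came to 0 with the slide as a block.

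Leaving out 1 sample at a time gave 665 to 2490 called genes between the parental groups (without maternal 2 and paternal 3, with 740 without maternal 1 and 881 without paternal 2). Between the F1 groups the range was 210 (without mendelian F1 1) to 2007 (without paternal 2). There the count was 657 without maternal 1, 374 and 479 without mendelian F1 2 and 3, 294 and 243 without non-mendelian F1 2 and 3 (483 higher and 24 lower without non-mendelian F1 1), and 1804 and 1612 without paternal 1 and 3. In mendelian F1 against paternal it was 3 (without any 1 of maternal 1 to 3, mendelian F1 2 or 3, or paternal 1 or 2) to 17 (without paternal 3), with 5 without mendelian F1 1 or non-mendelian F1 1. In mendelian F1 against maternal it was 1030 (without maternal 2) to 4197 (without paternal 2), with 1385 without maternal 1 and 1086, 1858 and 1971 without mendelian F1 1, 2 and 3. In non-mendelian F1 against paternal it was 157 (without non-mendelian F1 2) to 1254 (without paternal 1). There it was 284 and 214 without non-mendelian F1 1 and 3, 263 without paternal 2, 343, 360 and 369 without maternal 1, 2 and 3, and 371, 394 and 388 without mendelian F1 1, 2 and 3. In non-mendelian F1 against maternal it was 6 (without maternal 2) to 144 (without paternal 3), with 10 and 20 without maternal 1 and 3, 17, 52 and 11 without non-mendelian F1 1, 2 and 3, and 51 without mendelian F1 2. In F1 against parents it was 2 to 10, the latter without non-mendelian F1 2, and 3 without non-mendelian F1 3, paternal 1 or paternal 3, with 2 without each other sample.

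Lists passing ranged from 9 (without paternal 2) to 19 (without paternal 3) between the parental groups, from 7 (without paternal 3) to 16 (without mendelian F1 3) in mendelian F1 against paternal and from 9 (without maternal 2) to 22 (without maternal 3) in non-mendelian F1 against maternal. In mendelian F1 against paternal gpr-1 ranged from -0.043 (without mendelian F1 2) to 0.007 (without paternal 2), gpr-2 from -0.020 (without mendelian F1 2) to 0.069 (without mendelian F1 3), the detoxification median from -0.328 (without paternal 2) to 0.012 (without paternal 3, adjusted p = 0.0321) and the cytosolic ribosome median from -0.270 (without mendelian F1 1, adjusted p = 0.0266) to 0.159 (without paternal 1, adjusted p = 0.000184). In non-mendelian F1 against paternal lin-5 ranged from -0.032 (without paternal 1) to 0.032 (without non-mendelian F1 1), and the cell cycle median from -0.105 (without paternal 3) to 0.012 (without paternal 2). In non-mendelian F1 against maternal gpr-1 ranged from -0.017 (without maternal 2) to 0.071 (without non-mendelian F1 1). In F1 against parents gpr-1 ranged from -0.021 (without maternal 2) to 0.023 (without non-mendelian F1 1) and gpr-2 from -0.021 (without mendelian F1 2) to 0.024 (without mendelian F1 3).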

Other observations

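In this part the test of the slide and all tests of the X chromosome were chosen after the result was seen. Across all 4 groups, mtm-9 and unc-18 were low only on the arrays called maternal. The level of mtm-9 was 0.43 ± 0.08 in the paternal group, -5.37 ± 0.27 in the maternal group, -0.42 ± 0.23 in the mendelian F1 and 0.43 ± 0.12 in the non-mendelian F1. The chemoreceptor pseudogene srbc-15 was at background only in the paternal group (-9.36 ± 0.43), against -4.53 ± 0.21 in the mendelian F1. The male-fate gene her-1 stood at -3.16 in the maternal group and at -5.28, -5.30 and -5.08 in the paternal group, the mendelian F1 and the non-mendelian F1.

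Of 63 antimicrobial genes 26, such as nlp-25, nlp-34 and cnc-6, were called higher in the maternal than in the paternal group and 37 were not called, and the list passed with the preset correlation but not with an estimated correlation (adjusted p = 0.5). The slide as the whole cause is argued against, since with the slide as a block the median shift of the list was 1.045 against 1.105. A difference in developmental timing read from the sperm genes predicted a shift of the list mean of 0.153 ± 0.383, while 1.591 was seen. This argues against timing as the whole cause, but with so wide an error timing might still account for part of the pattern. The same prediction covered the collagens (0.911 ± 0.322 against 0.797) but not the neuropeptides (0.246 ± 0.098 against 0.604). A difference between the strains, which the design names, stays open and untested, as does the conflict of labels.

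Among X-linked genes, 195 such as unc-18 and srv-7 were called lower in the maternal than in the paternal group and 125 higher. Because the choice of called falls sets their median, falls were chosen without 1 maternal and 1 paternal array and measured on that pair (medians -1.097 to -0.576 over 9 pairs). For males among the maternal samples, the 25% point of the oocyte and eggshell genes (-0.219), taken as made only by hermaphrodites, was set against the falls. It lies above all these medians, and within each of the 9 pairs as well. The X-linked genes were chosen because they fell and the oocyte genes were not, so this test cannot decide. The oocyte genes themselves shifted little (median -0.14). The bounds of this test and the next were also set again 2 times after the values had been seen. Major sperm proteins (median 3.25) did not follow her-1: their mean was 3.21 to 4.69 in the non-mendelian F1, where her-1 stayed at -5.694 to -4.388. Yet her-1 (2.12 higher) and male neurons (0.70, camera adjusted p = 0.334) go with males, and a share of males stays open. For a lower dose of the whole X chromosome, the 25% point over all X-linked genes (-0.334) was set against the falls. That point lies above the medians of the falls too, although on 1 pair taken alone it lay below the median of the falls (gap -0.143). The falls are the low end of the X-linked genes by choice, so this test cannot decide. The median over all X-linked genes was -0.04, so the chromosome as a whole did not shift by as much as the falls. A smaller shift of the whole chromosome stays open. A maternal allele that is read less well by the probe or is less active in cis would put the mendelian F1 at -0.106 on the parental axis, but it lay at -0.39 ± 0.041. It lay as far to the paternal side over the called rises (-0.38), though not over the other falls (-0.12). The position is thus not particular to the X-linked falls, and its SD leaves out noise in the parental arrays, so this test cannot decide. A difference in regulation between the strains, in cis or not, stays open and untested, as does the conflict of labels.

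Each comparison of 3 against 3 samples was set against all 10 splits of its 6 samples. The real split gave the highest count in each, so 1 of 10 splits, itself, reached it, and 10 splits are too few to show more. The highest other count was 2 against 1611 between the parental groups, 4 against 1042 between the F1 groups and 1 against 8 in mendelian F1 against paternal. It was 1 against 2982 in mendelian F1 against maternal, 0 against 596 in non-mendelian F1 against paternal and 8 against 85 in non-mendelian F1 against maternal. For both F1 groups against both parental groups, 3 of 100 drawn regroupings of the 12 samples, the real one included, gave at least 9 called genes, with 1768 as the highest.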
